A study of Mus musculus with 16 samples.

How the data were processed

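RNA from 16 tumour samples of an orthotopic pancreatic cancer model in female C57BL/6 mice was measured on 1-colour Agilent mouse gene expression arrays: 6 samples from vehicle-treated animals, 5 taken 48 h after the start of ADH-503 treatment and 5 taken at 10 days. Group and time were taken from the treatment and time labels of each sample, and replicate numbers only name the arrays. The titles of the treated samples name the compound LA1, which was taken to be ADH-503, the treatment label of the same samples. The time label of the vehicle samples reads control, with no time, so they serve both times, and the age of their tumours against the treated ones is not known. Per the labels' protocols, total RNA was amplified as cDNA with a whole-transcriptome kit and labelled chemically with Cy5. The labels carry an ID number per sample and do not state whether each sample came from its own animal, so the p-values below measure the spread between these samples, part of which can be technical. The same ID number stands in the titles of vehicle replicate 2 and of 48 h replicate 5, while the description of the former gives another number, which no other sample carries; their arrays correlated at r = 0.949 across genes, and 5 of the 120 pairs of arrays correlated less, so both were kept, and each result was also computed without them.

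Scanner images were quantified with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes. Per the file headers, each spot's processed signal is a background-subtracted intensity on a linear scale, detrended over the surface of the array, with surrogate values put in for dim spots and no scaling between arrays, and probe positions are given on mouse genome build mm9. The authors also deposited a table of log2 values of the same arrays; it is quantile-normalized, since its 16 sorted columns differ by at most 0.0043 and each has a median of 10.190, and each column correlates with its own array's log2 processed signal at r = 0.998 or more. That table was used as an alternative source of values, and no column was left without a sample. No statistical test by the authors is stated in the sources used here.

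Each array holds 59305 spots, of which 3671 are control spots that were left out, and 56605 probes. The log2 processed signal was taken per spot, spots of 1 probe were averaged, and each array's 75th percentile over all probes was subtracted, so that values are log2 signal relative to that percentile. Outlier spots were left out, which removed 62 values among the genes tested, and no spot was saturated. The 75th percentile of the processed signal ran from 6315 to 8473 between arrays, and 74.9% to 81.2% of probes were well above background. Names came from a table of mouse genes on assembly GRCm38.p6, used for names only: 32994 probes were matched by accession and 10744 by symbol or synonym, and 12867 kept the name in the files. Of the 37008 names, each was represented by the probe with the highest mean signal over all arrays, and 30582 were tested because that probe was well above background on at least 5 of the 16 arrays. A gene's other probes are mentioned where they moved the opposite way. No fold is printed for a gene below background on every array of a group.

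Group differences were tested with limma 3.58.1 in R 4.3.3: lmFit on the 3 groups in 1 model without covariates, then robust eBayes without an intensity trend. P-values were 2-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The comparisons were 48 h against vehicle, 10 days against vehicle, and 10 days against 48 h. In total 25 pathway lists and 26 cell type lists, with 736 genes of which 701 were tested, were compared with the other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 51 lists. Beside it stand camera with an estimated correlation, limma's fry, and an exact 2-sided permutation test of each array's mean over the list, which could reach p = 0.00216 against vehicle and p = 0.00794 between the treated groups. A list's shift is the mean log2 fold change of its tested genes. The groups, comparisons, the tests named so far, gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined; some later tests, among them the estimated correlation in the blocked fit, splits within slides and leaving out arrays for lists that did not pass, were chosen after the results were seen.

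The rule for named genes takes, where none passes the threshold, the 5 genes per direction with the smallest p that have a symbol and are well above background on at least 3 arrays of each group. It adds Itgam and Itgb2, the genes of the integrin that ADH-503 binds, and up to 4 members with the smallest p from each list described; 1 gene taken by this rule is not reported here. The arrays lie on 2 slides, each scanned in its own session: slide 1 holds 1 vehicle, 4 of the 48 h and 3 of the 10 day arrays, and slide 2 holds 5, 1 and 2. Results are therefore given also with slide as a fixed block and within each slide, where slide 1 has a single vehicle array and slide 2 a single 48 h array whose spread is taken from the other arrays. With group in the model, 0 genes passed the adjusted threshold between slides. In limma 1593 genes had an unadjusted p under 0.05, where 1529 would by chance. In camera with the preset correlation 24 of the 51 lists passed, and no estimated correlation was computed for slides. Arrays correlated across genes at a mean r = 0.96155 within and r = 0.96158 between slides.

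The scripts were tested on simulated data with the measured means and spreads over the 30582 genes. At an adjusted p under 0.05, a log2 change of 1 was recovered for 52% of the changed genes at 48 h against vehicle, 67% at 10 days against vehicle and 58% at 10 days against 48 h, and a change of 2 for 91%, 84% and 87%. All 4 lists shifted by a log2 change of 0.5 were called in each of these 3 comparisons, and 0 of the 44 unshifted ones. Smaller list shifts were not simulated. The simulated genes varied independently, which those of the arrays do not. The alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the deposited log2 table, no filter and a stricter filter on dim probes, slide as a fixed or random block and within slide, only the 2 groups compared in the model, array weights, every probe, an intensity trend, leaving out both arrays with the shared number, and leaving out each array in turn. The mean of the acinar markers as a covariate was added after the data were seen. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.194 against vehicle and 0.203 between the treated groups.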

Results

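The series asks which genes change in pancreatic tumours at different times after treatment with ADH-503, a small molecule that activates CD11b, the integrin alpha M chain carried by neutrophils, monocytes and macrophages. Whole tumour RNA of an orthotopic mouse model was measured on 16 arrays, 6 from vehicle-treated animals, 5 at 48 h and 5 at 10 days of treatment. Over 30582 genes the arrays correlated with each other at r = 0.942 to 0.976. Arrays of the same group were no more alike than arrays of different groups, with mean r = 0.961 within and r = 0.962 between groups across genes, which are not independent replicates. The first 3 principal components held 19.4%, 12.6% and 9.05% of the variance, and the 3 groups overlapped on each of them.

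At 48 h no single gene differed from vehicle past the threshold, and the clearest shift of a gene group in camera was in the digestive enzymes of pancreatic acinar cells, though no list passed with an estimated correlation (adjusted p = 0.665 or more). The mean of 26 acinar markers was higher by 0.91 on the log2 scale, at 1.48 ± 0.26 (SD, n = 5) against 0.57 ± 0.66 (SD, n = 6), and all 5 treated arrays lay above the vehicle mean. Markers of red blood cells were lower by a log2 shift of -1.11 and those of endothelium by -0.39, while macrophage markers were higher by 0.089 and complement genes by 0.12. The chains of the drug's target did not differ past the threshold: Itgam, encoding CD11b, measured 5.11 ± 0.18 (SD, n = 5) against 5.11 ± 0.22 (SD, n = 5) in vehicle, where 1 outlier spot was left out, and its partner Itgb2 5.02 ± 0.09 (SD, n = 5) against 4.95 ± 0.16 (SD, n = 6). A further Itgam probe moved the opposite way at both times. These values are log2 signals relative to each array's 75th percentile.

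Of the acinar markers 24 of 26 were higher at 48 h, 12 of them at an unadjusted p under 0.05 in limma, and 0 passed when adjusted over the list alone or over all genes. Cela1, a pancreatic elastase whose probe lies on chromosome 15 from 100504871 to 100504930 (mm9), was higher by 0.74 ± 0.26 (SE), the chymotrypsin-like protease Ctrl by 1.47 ± 0.54 (SE) and the zymogen granule protein Zg16 by 1.06 ± 0.39 (SE). The list passed camera with adjusted p = 1.32e-19 (adjusted p = 0.665 with an estimated correlation; exact permutation p = 0.0195 before and 0.916 after adjustment over the lists). The shift was 0.57 with slide as a block, 0.84 within slide 1 and 1.05 within slide 2. In the blocked fit the list did not pass without vehicle replicate 1 or 48 h replicate 5, at 0.31 and 0.19.

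All 11 erythroid markers were lower at 48 h, 3 at an unadjusted p under 0.05 in limma. The alpha globin genes Hba-a1 and Hba-a2, near-identical copies that a probe may not tell apart, had log2 fold changes of -1.74 ± 0.73 (SE) and -1.96 ± 0.85 (SE). The beta globin gene Hbb-b1 had -2.26 ± 1.01 (SE), but it was well above background on 1 of 5 treated and 4 of 6 vehicle arrays only, so this value is uncertain. The list passed camera with adjusted p = 8.76e-05 (adjusted p = 0.665 with an estimated correlation; exact permutation p = 0.115), with 4 of 5 treated arrays below the vehicle mean. Its shift was -0.66 with slide as a block, 0.026 within slide 1 and -1.39 within slide 2. Leaving out 1 array at a time, the blocked shift ran from -0.98 to -0.25, and the blocked call was lost for 6 of the 16 arrays. Vehicle replicate 3 lay 2.36 above the mean of the other vehicle arrays, and without it the shift was -0.72 with camera adjusted p = 0.0550.

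Among macrophage markers 14 of 15 were higher at 48 h, with a list mean of 3.88 ± 0.05 (SD, n = 5) against 3.79 ± 0.10 (SD, n = 6) and all 5 treated arrays above the vehicle mean. C1qa and C1qb, chains of complement C1q made by tissue macrophages, were higher by 0.23 ± 0.11 (SE) and 0.14 ± 0.09 (SE), and the Fc receptor gene Fcgr3 by 0.16 ± 0.10 (SE). The 15 complement genes, 3 of which are also in the macrophage list, had 12 members higher, among them C4b by 0.38 ± 0.23 (SE). Camera gave adjusted p = 0.00234 for macrophages and 0.00783 for complement (adjusted p = 0.665 with an estimated correlation for both; exact permutation p = 0.0952 and p = 0.180). The macrophage shift was 0.074 with slide as a block, where it no longer passed, 0.062 within slide 1 and 0.055 within slide 2. The complement shift was -0.0070 with the block, 0.0096 within slide 1 and 0.061 within slide 2. Over all genes the median log2 fold change was 0.072 within slide 1 and -0.040 within slide 2. Within slide 1 both lists thus lay below the median gene, so their positive shifts there show no rise against other genes. Without vehicle replicate 4 neither list passed, with shifts of 0.050 and 0.10, and complement did not pass without 48 h replicate 3 or 4 either, at 0.069 and 0.084.

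Endothelial markers were lower in 12 of 14 cases, and all 5 treated arrays lay below the vehicle mean. The junction genes Esam and Cdh5 had log2 fold changes of -0.66 ± 0.30 (SE) and -0.82 ± 0.53 (SE), and Kdr, a receptor for VEGF, -0.53 ± 0.26 (SE). Cdh5 was above background on 3 of 5 treated and 5 of 6 vehicle arrays. All 20 ribosomal protein genes were higher by small amounts, with a shift of 0.069 and Rps6, Rps2 and Rpl18 at 0.12 ± 0.14 (SE), 0.13 ± 0.12 (SE) and 0.08 ± 0.09 (SE). Camera gave adjusted p = 0.0157 for both lists (adjusted p = 0.665 for endothelium and 0.960 for ribosomal proteins with an estimated correlation; exact permutation p = 0.154 and p = 0.459). The endothelial shift was -0.47 with slide as a block, -0.52 within slide 1 and -0.35 within slide 2, and the ribosomal shift 0.17, 0.0098 and 0.25. Housekeeping controls moved the same way as the macrophage and ribosomal lists, with 11 of 12 genes higher and a shift of 0.055 (camera adjusted p = 0.156), and 0.13 with slide as a block (camera adjusted p = 0.00438; adjusted p = 0.646 with an estimated correlation), 0.057 within slide 1 and 0.099 within slide 2. Within slide 1 the ribosomal and housekeeping shifts lay below the median of 0.072 over all genes. The endothelial list did not pass without vehicle replicate 1, 2 or 4, at -0.37, -0.29 and -0.26. The ribosomal list did not pass without vehicle replicate 3 or 4 or 48 h replicate 5, at 0.065, 0.010 and 0.024.

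The 10 single genes with the smallest p at 48 h did not pass the adjusted threshold. Those higher were the long non-coding RNA Particl by 0.79 ± 0.19 (SE), the neurotensin receptor Ntsr1 by 0.78 ± 0.22 (SE), the zinc finger gene Zfp438 by 0.75 ± 0.22 (SE), the Rab11 effector Rab11fip2 by 0.41 ± 0.12 (SE) and the ubiquitin ligase scaffold Cul5 by 0.40 ± 0.11 (SE). Lower were Kdm8 at -1.08 ± 0.26 (SE), the testis gene Tcp11 at -1.01 ± 0.27 (SE), the tight junction claudin Cldn19 at -0.98 ± 0.23 (SE), the olfactory receptor Olfr213 at -0.68 ± 0.19 (SE) and the glycine receptor gene Glra4 at -0.58 ± 0.15 (SE). Cldn19 was above background on 3 of 5 treated arrays, and Ntsr1 and Zfp438 on 4 of 6 vehicle arrays. A further probe of Rab11fip2 and one of Tcp11 moved the opposite way. Each of the 10 changes kept its sign with slide as a block, where they ran from -1.07 to 0.93, and within both slides. The change of Tcp11 was -0.65 with the block. These genes were picked for their p on the same arrays, so a kept sign is no independent support. Of the 16 list members named above, all kept their sign with the block, but C4b and Fcgr3 changed sign within slide 1, at -0.02 and -0.05, and Cdh5 within slide 2, at 0.18. Within slide 1 Hbb-b1 was not well above background on the vehicle array, so no value is given. Blocked values differed by over 1.5 times for the globin genes Hba-a1, Hba-a2 and Hbb-b1, at -1.05, -1.17 and -0.68, for C4b, at 0.16, and for Rps2, Rps6 and Rpl18, at 0.26, 0.32 and 0.15.

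In limma 0 of 30582 genes passed at 48 h, 783 had an unadjusted p under 0.05 where 1529 would by chance, and the smallest adjusted p was 0.99998. Camera called 6 of 51 lists, 4 higher and 2 lower, and camera with an estimated correlation, fry and the adjusted permutation test called 0. Of 100 splits of the same 11 arrays 68 gave as many lists, so these calls cannot be set apart from chance. The splits were drawn at random beside the real one. The real split is included here and in all later counts of splits that gave as many lists. Camera called 15 lists with slide as a block, 4 of them shared with the 6, and 5 of the 30 splits that keep each slide's group sizes gave as many. Among those the block added were inflammatory cytokines, at -0.33 in place of -0.14, the intestinal epithelium list, at -0.64 in place of -0.44, and oxidative phosphorylation, at 0.13 in place of 0.039. None of the 15 passed with an estimated correlation (adjusted p = 0.646 or more). Within slides 1 and 2 these 3 were at -0.0065 and -0.43, -0.39 and -0.41, and 0.010 and 0.12. In the blocked fit the intestinal list did not pass without vehicle replicate 1 or 4 or 48 h replicate 4, at -0.83, -0.49 and -0.49. Without single arrays the blocked cytokine shift ran from -0.52 to -0.25 and that of oxidative phosphorylation from 0.094 to 0.21, with the calls kept. Unblocked, they ran from -0.22 to -0.049 and from -0.0058 to 0.074. Camera called 2 lists without vehicle replicate 4, 10 without 48 h replicate 3, and 2 with quantile normalization, of which acinar cells were higher and erythroid cells lower.

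**Figure D1:**
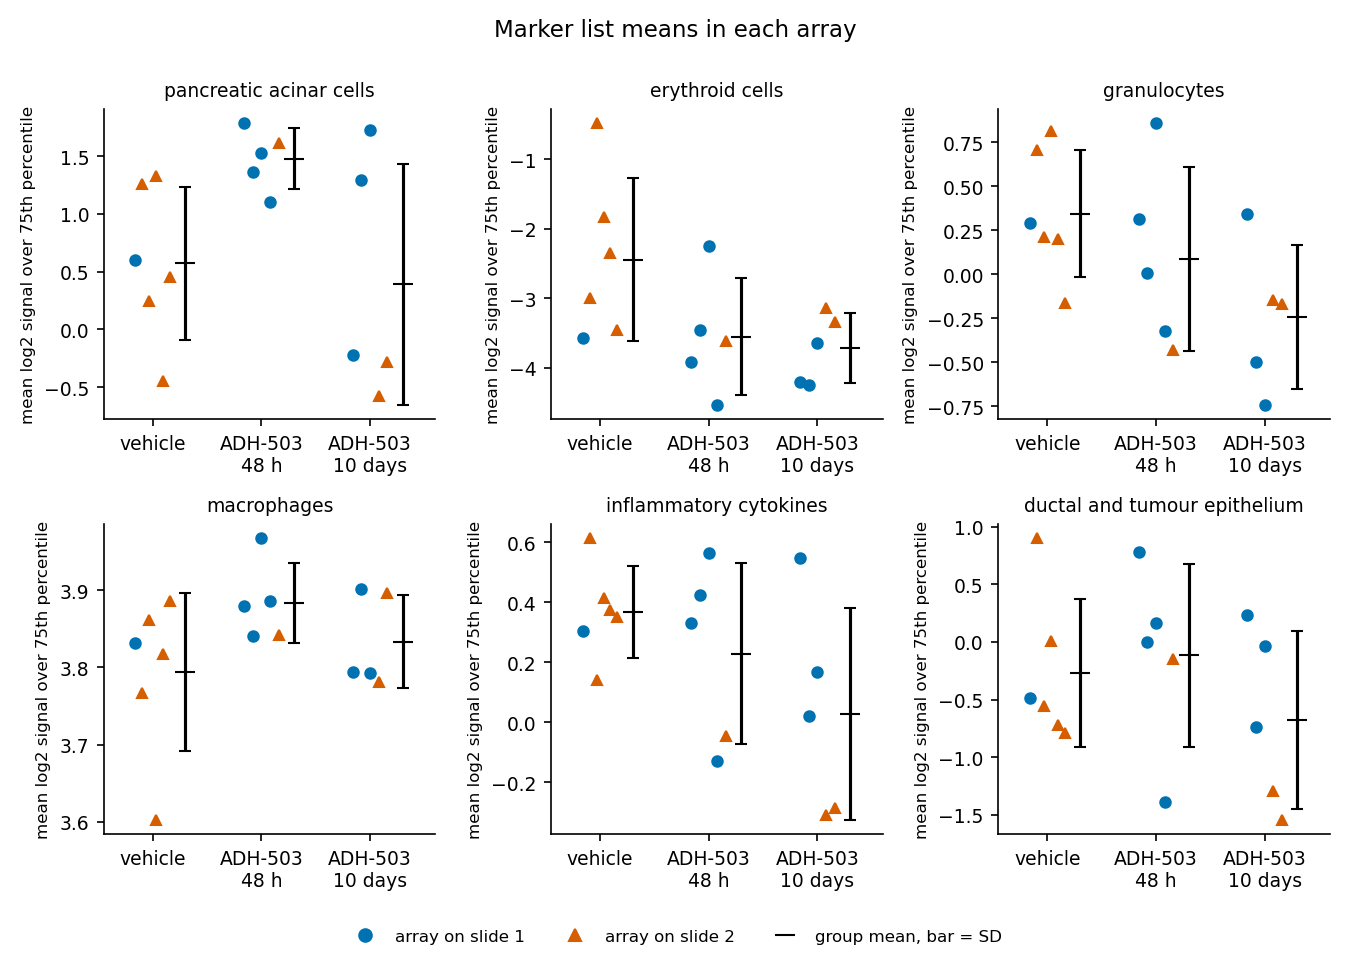
Mean of the log2 signals of each marker list, relative to the array's 75th percentile, for every array (circles on slide 1, triangles on slide 2) by group, with group mean and SD. All 5 arrays at 48 h had acinar means above the vehicle mean of 0.57, and granulocyte means at 10 days averaged -0.24 against 0.34 in vehicle.

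At 10 days, too, no single gene passed, and the gene groups that differed from vehicle in camera were all lower, though none of them passed with an estimated correlation (adjusted p = 0.722 for each). The largest shifts were in erythroid markers, at -1.27, in the intestinal epithelium list, at -0.70 and led by the antimicrobial lectins Reg3g and Reg3b, in mast cells, at -0.60, and in granulocytes, at -0.59. Inflammatory cytokines were lower by a log2 shift of -0.34, ductal and tumour epithelium by -0.40, and proliferation genes by -0.19. Immediate early and heat shock genes were lower by -0.11 and genes of the unfolded protein response by -0.12. Itgam measured 5.10 ± 0.05 (SD, n = 5) and Itgb2 4.92 ± 0.15 (SD, n = 5), with log2 fold changes of -0.02 ± 0.12 (SE) and -0.02 ± 0.10 (SE) against vehicle.

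All 16 granulocyte markers were lower at 10 days, with a list mean of -0.24 ± 0.41 (SD, n = 5) against 0.34 ± 0.36 (SD, n = 6). All 5 treated arrays lay below the vehicle mean, but 10 day replicate 1 only just, at 0.342. That array lay above vehicle replicates 1, 3, 5 and 6. The neutrophil granule genes Ltf and Camp had log2 fold changes of -2.00 ± 0.54 (SE) and -1.58 ± 0.63 (SE). The Ltf probe lies on chromosome 9 from 110942873 to 110942932 (mm9). Of the 16 genes 3 had an unadjusted p under 0.05 in limma, 1 passed when adjusted over the list alone, and 0 passed over all genes. The list passed camera with adjusted p = 0.000121 (adjusted p = 0.722 with an estimated correlation; exact permutation p = 0.0411 before and 0.621 after adjustment over the lists). Its shift was -0.63 with slide as a block, -0.59 within slide 1 and -0.51 within slide 2.

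Of 19 inflammatory cytokine genes 17 were lower at 10 days. Il12b, encoding the p40 chain shared by IL-12 and IL-23 (probe on chromosome 11 from 44226781 to 44226840, mm9), had -0.83 ± 0.18 (SE). It measured -3.03 ± 0.35 (SD, n = 5) against -2.20 ± 0.31 (SD, n = 6) in vehicle. The prostaglandin synthase gene Ptgs2 had -0.54 ± 0.16 (SE). When adjusted over the list alone 2 genes passed, and over all genes 0. Mast cell markers were lower in 10 of 11 cases, among them the proteases Mcpt4 at -1.12 ± 0.42 (SE) and Mcpt1 at -0.94 ± 0.46 (SE). Camera gave adjusted p = 9.51e-06 for cytokines and 0.000442 for mast cells (adjusted p = 0.722 with an estimated correlation for both; exact permutation p = 0.0693 and p = 0.132), with 4 of 5 treated arrays below the vehicle mean in each. The cytokine shift was -0.47 with slide as a block, -0.058 within slide 1 and -0.68 within slide 2, and the mast cell shift -0.75, -1.10 and -0.42. Without vehicle replicate 2 the mast cell shift was -0.36 and still passed.

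All 11 erythroid markers were lower at 10 days, with Hba-a1 at -1.89 ± 0.73 (SE) and Hba-a2 at -2.09 ± 0.85 (SE), and all 5 treated arrays below the vehicle mean. Camera gave adjusted p = 8.49e-07 (adjusted p = 0.722 with an estimated correlation; exact permutation p = 0.0433). The shift was -0.97 with slide as a block, -0.47 within slide 1, -1.02 within slide 2 and -0.88 without vehicle replicate 3, which had the highest erythroid mean.

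The intestinal epithelium list had 9 of 10 genes lower, and 2 passed when adjusted over the list alone. These were Reg3g at -2.33 ± 0.66 (SE), above background on 4 of 5 treated arrays, and Reg3b at -1.60 ± 0.47 (SE), secreted lectins that inflamed pancreas also makes. Their neighbour on chromosome 6, Reg3a, was at -1.57 ± 0.42 (SE); their probes lie between 78323323 and 78416479 (mm9). Of the ductal and tumour epithelium genes 20 of 22 were lower, with Lcn2, which granulocytes also make, at -0.52 ± 0.36 (SE), and 3 of 5 treated arrays lay below the vehicle mean. Camera gave adjusted p = 0.00177 for the intestinal and 0.00558 for the ductal list (adjusted p = 0.722 with an estimated correlation for both; exact permutation p = 0.0974 and p = 0.379). The shifts were -0.83 and -0.60 with slide as a block, -0.31 and 0.31 within slide 1, and -1.20 and -1.19 within slide 2. The intestinal list did not pass without vehicle replicate 4, at -0.52, or 10 day replicate 5, at -0.43. The ductal list did not pass without vehicle replicate 2 or 4, at -0.17 and -0.35, or without 10 day replicate 4 or 5, at -0.25 and -0.18, nor with the acinar mean as a covariate, at -0.30, and was at -0.63 without 10 day replicate 1.

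Proliferation genes were lower in 27 of 30 cases, with the DNA helicase subunit Mcm5 at -0.62 ± 0.22 (SE) and the topoisomerase Top2a at -0.47 ± 0.19 (SE). Immediate early and heat shock genes were lower in 15 of 20 cases, with Dusp1 at -0.29 ± 0.13 (SE) and Egr2 at -0.24 ± 0.13 (SE), and genes of the unfolded protein response in 14 of 16, with Chac1 at -0.39 ± 0.20 (SE) and Herpud1 at -0.28 ± 0.13 (SE). Camera gave adjusted p = 3.37e-06, 0.0376 and 0.0450 (adjusted p = 0.722 with an estimated correlation for all 3; exact permutation p = 0.141, 0.238 and 0.232). Blocked on slide, the shifts were -0.17, -0.16 and -0.047, the last no longer passing; within slide 1 they were -0.51, 0.061 and -0.22, and within slide 2 0.016, -0.25 and 0.083. The proliferation shift was -0.12 without 10 day replicate 2 and still passed. With the block it ran from -0.26 to -0.052 when single arrays were left out, and the call was lost for 1 of them. The immediate early list did not pass without vehicle replicate 1, 2 or 6, 48 h replicate 4 or 10 day replicate 4, with shifts from -0.12 to -0.058. The unfolded protein list did not pass without vehicle replicate 1, 5 or 6, 48 h replicate 4 or 5, or 10 day replicate 1, 2 or 3, with shifts from -0.13 to -0.081, and was at -0.20 without 10 day replicate 5.

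The 10 single genes with the smallest p at 10 days did not pass either. Higher were the galanin receptor Galr2 by 1.86 ± 0.35 (SE), the non-coding RNA Mexis by 0.95 ± 0.24 (SE), the histone methyltransferase gene Setmar by 0.93 ± 0.22 (SE), the phosphatase Ppef2 by 0.90 ± 0.20 (SE) and Spata45 by 0.82 ± 0.21 (SE). Beside Il12b and Reg3a, those lower were Lhfpl4 at -2.05 ± 0.52 (SE), the melatonin receptor Mtnr1a at -1.50 ± 0.37 (SE) and the olfactory receptor Olfr1247 at -1.38 ± 0.29 (SE). Galr2 was above background on 5 of 6 vehicle arrays, Lhfpl4 on 4 of 5 and Mtnr1a on 3 of 5 treated arrays. Each of the 10, picked for its p on these same arrays, kept its sign with slide as a block and within both slides, with blocked changes from -1.69 to 1.75. So did the list members named at 10 days, whose blocked changes ran from -2.82 for Reg3g to -0.17 for Herpud1.

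In limma 0 of 30582 genes passed at 10 days, 1082 had an unadjusted p under 0.05 where 1529 would by chance, and the smallest adjusted p was 0.760. Camera called 9 of 51 lists, and camera with an estimated correlation, fry and the adjusted permutation test called 0; 53 of 100 random splits of the 11 arrays gave as many lists, so these calls cannot be set apart from chance. Camera called 16 lists with slide as a block, 8 of them shared with the 9, and 13 of the 84 splits that keep each slide's group sizes gave as many. Among those the block added were acinar cells, at -0.42 in place of -0.18 (camera adjusted p = 0.00118; adjusted p = 0.715 with an estimated correlation), with 0.33 within slide 1 and -0.996 within slide 2, myeloid-recruiting chemokines, at -0.25 in place of -0.15, and TGF-beta response, at -0.37 in place of -0.23. None of the 16 passed with an estimated correlation (adjusted p = 0.403 or more). Single arrays turn the acinar value, which without the block was 0.058 without 10 day replicate 4 and -0.52 without 10 day replicate 3. In the blocked fit it did not pass without vehicle replicate 4 or 10 day replicate 1 or 4, at -0.27, -0.26 and -0.14. Within slides 1 and 2 the chemokines were at 0.064 and -0.41 and TGF-beta response at -0.13 and -0.48. With the block the chemokines did not pass without 10 day replicate 4, at -0.18, nor TGF-beta response without each of 12 of the 16 arrays. Camera called 15 lists without vehicle replicate 5 or without 10 day replicate 5.

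**Figure D2:**
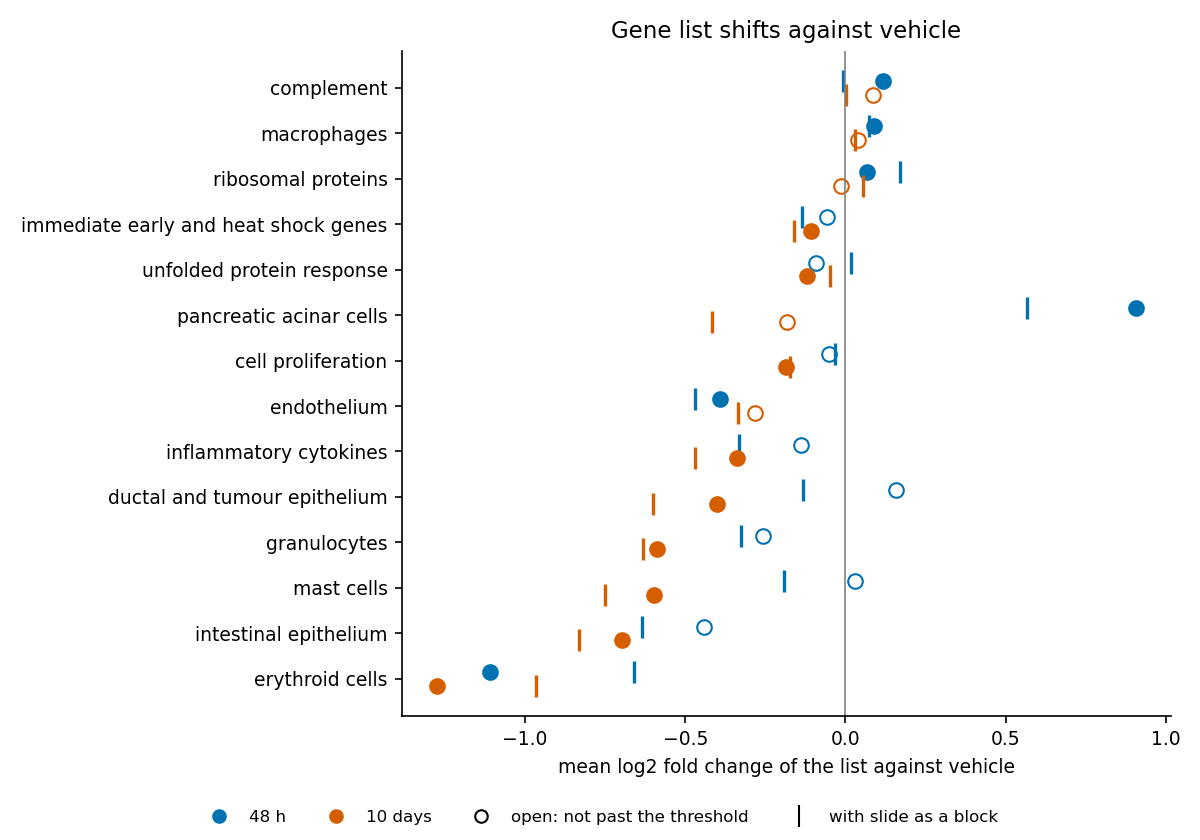
Mean log2 fold change against vehicle of each list called at 48 h (blue) or 10 days (orange), filled where camera's adjusted p passed 0.05 and open where not, with the value with slide as a block as a tick. The acinar shift was 0.91 at 48 h and -0.18 at 10 days (0.57 and -0.42 with the block), and erythroid shifts were -1.11 and -1.27.

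Between the treated groups, 10 days against 48 h, none of the lists called passed camera with an estimated correlation (adjusted p = 0.685 or more). Among these lists the acinar markers differed most. Their mean was 0.39 ± 1.05 (SD, n = 5) at 10 days against 1.48 ± 0.26 (SD, n = 5) at 48 h, a shift of -1.09, with 24 of 26 genes lower, 21 of them at an unadjusted p under 0.05 in limma, and 4 of 5 arrays at 10 days below the 48 h mean. The 10 day arrays lay apart in 2 sets: replicates 2 and 3, both on slide 1, at 1.29 and 1.73, and the other 3 between -0.58 and -0.22. The sets do not follow the slide, since replicate 1, at -0.22, is on slide 1 too. Vehicle replicates 2 and 4, on slide 2, were at 1.26 and 1.33. Mast cells, ductal and tumour epithelium, granulocytes, TGF-beta response and epithelial-mesenchymal transition regulators were lower at 10 days, at -0.63, -0.56, -0.33, -0.32 and -0.27. So were T cells, inflammatory cytokines, proliferation genes, hypoxia and glycolysis, oxidative phosphorylation and ribosomal proteins, at -0.24, -0.20, -0.13, -0.11, -0.098 and -0.082. The type I interferon response was higher, at 0.15, with 26 of 32 genes higher.

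Camera's adjusted p was 1.50e-20 for acinar cells, 2.16e-05 for ductal epithelium, 0.000489 for proliferation, 0.000545 for mast cells and between 0.00685 and 0.0424 for the other lists. With an estimated correlation the adjusted p was 0.749 for interferon and 0.685 for each of the other 12, and exact permutation p ran from 0.0952 to 0.460. The acinar shift was -0.98 with slide as a block, -0.51 within slide 1 and -2.05 within slide 2, where 48 h has 1 array. The ductal shift was -0.47, -0.071 and -1.27, that of mast cells -0.56, -0.88 and 0.21, and that of granulocytes -0.31, -0.52 and 0.27. For proliferation it was -0.14, -0.24 and 0.039, for cytokines -0.14, -0.051 and -0.25, for TGF-beta response -0.25, -0.21 and -0.29, and for hypoxia -0.084, -0.18 and 0.22. Epithelial-mesenchymal regulators gave -0.23, -0.19 and -0.26, T cells -0.25, -0.21 and -0.25, oxidative phosphorylation -0.13, -0.19 and -0.010, ribosomal proteins -0.11, -0.13 and -0.12, and interferon 0.14, 0.14 and 0.12, in the same order. With slide as a block only 6 of the 13 calls were kept, among them those of ductal epithelium, mast cells, proliferation and oxidative phosphorylation. Without the block, each list apart from the acinar and ductal ones lost its call when 1 or more single arrays were left out. The ductal and acinar means correlated at r = 0.577 over the 16 arrays. With the acinar mean as a covariate the ductal shift turned from -0.56 to 0.047 and that of interferon from 0.15 to -0.0068. The acinar mean itself differed between these groups, so the covariate takes out part of the shift of any list that follows it. These turns therefore do not decide what lies behind either shift.

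The single genes with the smallest p, which did not pass, were higher at 10 days for Galr2 by 2.15 ± 0.37 (SE), Psors1c2 by 1.83 ± 0.34 (SE), Ppef2 by 1.14 ± 0.21 (SE), the receptor Gpr3 by 1.08 ± 0.21 (SE) and the synaptic adhesion gene Lrfn1 by 0.51 ± 0.10 (SE). The Galr2 probe lies on chromosome 11 from 116144714 to 116144773 (mm9) and was above background on 4 of 5 arrays at 48 h. Lower were Ccl21a, a chemokine for CCR7-bearing lymphocytes and dendritic cells with close copies in the genome, at -1.84 ± 0.46 (SE), Reg3a at -1.59 ± 0.44 (SE), its family member Reg3d at -1.39 ± 0.39 (SE), the lipid droplet gene Fitm2 at -0.88 ± 0.25 (SE) and Rhbdd2 at -0.59 ± 0.15 (SE), whose other probe moved the opposite way. All 10, picked for their p on these same arrays, kept their sign with slide as a block and within both slides, with blocked changes from -1.80 to 2.20. In limma 0 genes passed, 1062 had an unadjusted p under 0.05 where 1529 would by chance, and the smallest adjusted p was 0.382. Camera called 13 of 51 lists, 1 higher and 12 lower, and the other list tests called 0; 32 of 100 random splits of the 10 arrays gave as many. It called 7 lists with slide as a block, 6 of them shared with the 13, and 60 of 100 splits that keep each slide's group sizes gave as many. With quantile normalization it called 5, interferon higher and 4 lower, among them acinar and ductal cells.

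**Figure D3:**
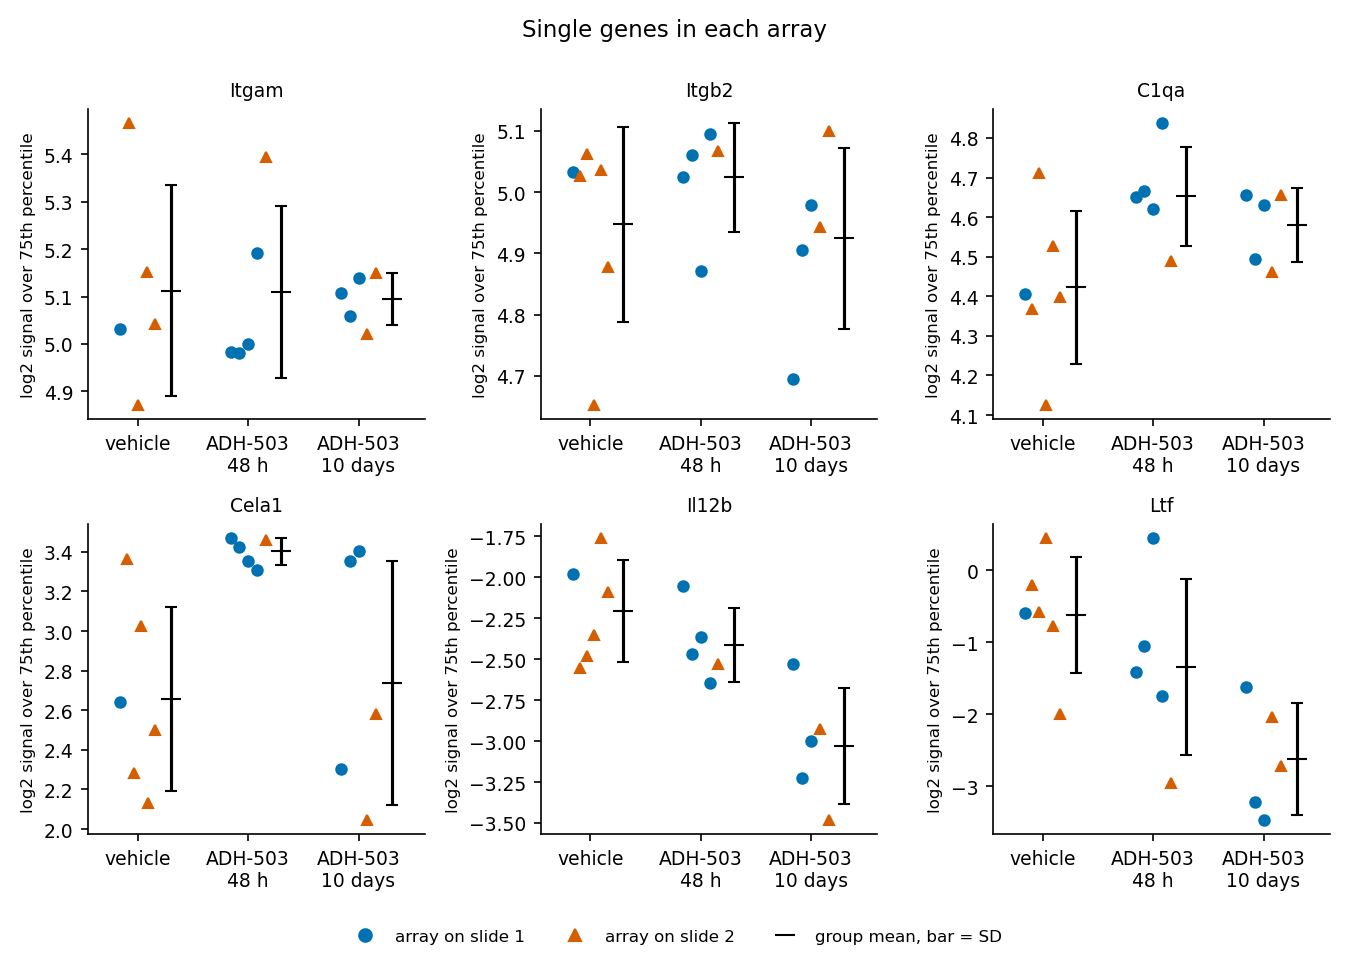
Log2 signal relative to the array's 75th percentile of 6 genes for every array (circles on slide 1, triangles on slide 2) by group, with group mean and SD. Itgam averaged 5.11 in vehicle, 5.11 at 48 h and 5.10 at 10 days, Cela1 measured 3.40 at 48 h against 2.66 in vehicle, and Il12b -3.03 at 10 days against -2.20 in vehicle; none of these genes passed the adjusted threshold.

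Whether both times moved the same genes was asked through the log2 fold changes at 48 h and at 10 days, which share the 6 vehicle arrays. They correlated at r = 0.414 across 30582 genes, with a covariance of 0.0423. Simulated unchanged groups that shared simulated vehicle arrays gave r = 0.454 and 0.0533. Of 100 random regroupings of the arrays 60 gave a correlation as high. With the vehicle arrays split 3 and 3, over 20 splits, the mean r was -0.054, from -0.23 to 0.11. At an unadjusted p under 0.05 in limma 68 genes were higher and 75 lower at both times. Independent lists would share 4.69 and 9.18, and the simulation with shared vehicle arrays gave 151 and 154. Its genes varied independently and were fitted without the robust step. The measured arrays had 783 genes under that p at 48 h and 1082 at 10 days, where 1529 would by chance. The measured counts can therefore not be set against the simulated ones. The correlation was 0.577 with slide as a block, 0.805 within slide 1, where both times share 1 vehicle array, and 0.311 within slide 2. Unchanged groups were not simulated for the blocked and within-slide fits, so these values cannot be set against 0.454.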

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

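Several tests named here were chosen only after the results were seen. They include the test of slide for the acinar markers, the splits within slides and the acinar mean as a covariate. The estimated correlation in the blocked fit and the islet values without single arrays were chosen later too. Among the list shifts that differed between the 10 day and 48 h arrays in camera were those of acinar cells at -1.09, mast cells at -0.63, ductal and tumour epithelium at -0.56, granulocytes at -0.33, TGF-beta response at -0.32 and epithelial-mesenchymal transition regulators at -0.27. With an estimated correlation neither these nor the smaller ones passed (adjusted p = 0.685 or more). Smaller ones were those of T cells at -0.24, inflammatory cytokines at -0.20, cell proliferation at -0.13, hypoxia and glycolysis at -0.11, oxidative phosphorylation at -0.098, ribosomal proteins at -0.082 and type I interferon response at 0.15. Chance cannot be excluded for their number. Of 100 splits of the 10 arrays, the real one included, 32 gave as many as the real 13 lists, and the highest other split gave 24. With slide as a block 7 lists passed, and 60 of 100 splits that keep each slide's group sizes gave as many, with 21 in the highest other. In that blocked fit the ductal call was lost without 1 of the 16 arrays, the proliferation call without 2 and the mast cell call without 3. The blocked shifts then ran from -0.79 to -0.28 for the ductal list and from -0.21 to -0.059 for proliferation. Leaving out 1 array at a time without the block, acinar and ductal lists passed throughout. The ductal shift was -0.33 and -0.88 without 48 h replicate 1 or 4 and -0.34 without 10 day replicate 5. It turned to 0.047 with the acinar mean as a covariate, which itself differed between these groups. Mast cells did not pass without 48 h replicate 1, at -0.43, and proliferation without 10 day replicate 1 or 2, at -0.087 and -0.065; proliferation was at -0.084 and -0.20 without 48 h replicate 3 or 4 and still passed. The other lists lost the call for several arrays. Without 48 h replicate 1, 2 or 3 these were granulocytes, at -0.27, -0.35 and -0.14, cytokines, at -0.17, -0.15 and -0.12, TGF-beta response, at -0.24, -0.28 and -0.26, and epithelial-mesenchymal regulators, at -0.16, -0.22 and -0.24. Hypoxia did not pass without 48 h replicate 1 or 3, at -0.082 and -0.028, T cells without 48 h replicate 1, 3 or 4, at -0.22, -0.17 and -0.25, and interferon without 48 h replicate 1 or 2, at 0.10 and 0.090. Oxidative phosphorylation did not pass without 48 h replicate 3, at -0.059, and ribosomal proteins without 48 h replicate 5, at -0.037. Without 10 day replicate 2, 3 or 4 neither granulocytes (-0.27, -0.20 and -0.35), hypoxia (-0.065, -0.090 and -0.072), T cells (-0.20, -0.19 and -0.16) nor TGF-beta response (-0.33, -0.31 and -0.26) passed. Without 10 day replicate 1, 2 or 3 neither oxidative phosphorylation (-0.053, -0.076 and -0.078) nor ribosomal proteins (-0.053, -0.061 and -0.060) passed. Epithelial-mesenchymal regulators and interferon did not pass without 10 day replicate 2, 4 or 5, at -0.20, -0.26 and -0.18 and at 0.083, 0.14 and 0.14, nor cytokines without 10 day replicate 4 or 5, at -0.12 for both. T cells also lost the call without vehicle replicate 2 or 6, and TGF-beta response without vehicle replicate 6, arrays that enter only through the spread. Other arrays left out gave larger shifts, with the call kept: without 10 day replicate 1 T cells were at -0.38, cytokines at -0.33 and hypoxia at -0.19, without 48 h replicate 5 hypoxia at -0.20, and without 10 day replicate 5 ribosomal proteins at -0.14 and oxidative phosphorylation at -0.15.

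The acinar markers were higher at 48 h than in vehicle by 0.91 and lower at 10 days than at 48 h. Slides hold unequal shares of the groups, and with slide as a block the shift at 48 h was 0.57 ± 0.51 (SE) over array means in place of 0.91 ± 0.44 (SE), a ratio of 0.62; this does not decide how much the slides contribute, since the difference lies within the standard errors. Normal pancreas in the tumour piece may be a source, since it would bring islet transcripts along: over the 16 arrays the acinar and islet means gave Spearman's rho = 0.371 (permutation p = 0.157) and Pearson's r = 0.355 (permutation p = 0.179, adjusted p = 0.179 for both), r = 0.278 without the 2 arrays farthest from the acinar median, r = -0.175 within slide 1 and 0.581 within slide 2, and r = 0.592 for deviations from group means; yet islet markers were not higher at 48 h, at -0.30 (exact permutation p = 0.323) and at -0.65 with slide as a block (camera adjusted p = 0.0407; adjusted p = 0.646 with an estimated correlation), with 0 of 5 treated arrays above the vehicle mean, though the value was -0.18 and -0.15 without vehicle replicate 1 or 4 and the blocked call was lost without each of 9 of the 16 arrays, so the values point both ways and leave it open. All 26 acinar genes belong to normal pancreas, the organ that holds the tumour, and none of them is in another list. An effect of treatment on acinar tissue at 48 h stays open too, and was not tested apart from these.

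Within groups, 7 of 246 sets of values had 1 array far apart from the others, where 12.3 would by chance. The granule gene Camp was 2.25 higher on 48 h replicate 3 than the mean of the other 48 h arrays. Psors1c2 differed by -1.40 on 10 day replicate 2 and Reg3d by 1.12 on 10 day replicate 3 from the other 10 day arrays. On vehicle replicate 3, Ptgs2 differed by -0.43 from the other vehicle arrays. On vehicle replicate 4, C1qb differed by -0.28 and the mean of the oxidative phosphorylation genes by -0.27. On vehicle replicate 2 the mean of the epithelial-mesenchymal transition regulators was 0.84 higher than on the other vehicle arrays.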

How the results depend on the processing

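The acinar marker mean as a covariate was the 1 alternative chosen after seeing the data. No paired analysis was possible because only 1 number is shared by samples of different groups. Dim spots limit what can be seen: at most 81.2% of probes were well above background. Over the 16 settings other than leaving out an array, the 28 list shifts called kept both direction and call in 342 values, lost the call in 92 and changed sign in 14; the named genes had no call to lose. The cause was not tested for any of these except where fewer arrays are named. Lists called at 48 h numbered 6, and 2 with quantile normalization, 2 with the authors' deposited table, 15 with slide as a block, 3 within slide 1, 10 over every probe and 16 with the acinar covariate. At 10 days they numbered 9, and 16 with slide as a block. Between 10 days and 48 h they numbered 13, and 5 with quantile normalization and 5 with the authors' table. With slide as a block they numbered 7, and 4 within slide 2, where fewer arrays remain. Without both arrays with the shared number 9, 6 and 15 lists were called in these 3 comparisons. Of the 28 calls 6 were lost in that setting. Leaving out each array in turn gave 2 to 10 lists at 48 h, 7 to 15 at 10 days and 5 to 15 between the treated groups (at most 7 without 48 h replicate 1 or 3 or 10 day replicate 2, 3 or 4), and 0 to 1 genes in each comparison.

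Without a filter on dim probes 1 gene passed in limma at 48 h and 1 at 10 days, 4930448H16Rik both times, and with only the 2 groups compared 3 passed between 10 days and 48 h, Dnaaf4, BE945716 and 2210414B05Rik. These were named after their values were seen, and each was below background on all arrays at 48 h. Without vehicle replicate 1 BE945716 passed, without vehicle replicate 5 Dnaaf4, both at 48 h and between the treated groups, and without 10 day replicate 4 A630052C17Rik at 10 days. The correlation of the 48 h and 10 day changes, r = 0.414, was 0.577 with slide as a block, 0.805 within slide 1 and 0.279 with the acinar covariate. Unchanged groups were not simulated in these settings, so the values do not show whether both times moved the same genes. Within slide 2 these shifts changed sign: proliferation to 0.039 against 48 h and 0.016 against vehicle, granulocytes to 0.27, hypoxia to 0.22 and mast cells to 0.21 between the treated groups, and unfolded protein response at 10 days to 0.083. Within slide 1, which has 1 vehicle array, the median over all genes was 0.13 at 10 days and 0.072 at 48 h. There ductal epithelium at 10 days turned to 0.31, erythroid cells at 48 h to 0.026 and immediate early genes at 10 days to 0.061. Complement at 48 h turned to -0.0070 with slide as a block. The acinar covariate removes the acinar list by construction and takes out part of the shift of lists that follow it. With this covariate acinar cells turned to -0.0071 at 48 h and 0.0032 between the treated groups. Ductal epithelium turned to 0.047 and interferon to -0.0068, both between the treated groups.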

Other observations

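The test without vehicle replicate 3, the account of the split with most genes, the splits within slides and the values without single arrays in the first 2 paragraphs were chosen only after the results were seen. Lymphoid and dendritic cell markers showed no shift that passed against vehicle with all arrays in. T cell markers, such as the CD3 chains, had a mean log2 fold change of 0.052 at 48 h (camera adjusted p = 0.663) and -0.19 at 10 days (camera adjusted p = 0.143), and NK cells 0.025 and -0.31 (camera adjusted p = 0.763 and 0.194). Conventional dendritic cells were at -0.15 and -0.068 (camera adjusted p = 0.420 and 0.934), and B cells at 0.14 and 0.051. Regulatory T cells were at -0.049 and -0.21 (camera adjusted p = 0.620 and 0.0889). Leaving out 1 array at a time, T cells at 10 days ran from -0.33 to -0.076 and passed without each of 3 arrays. Regulatory T cells at 10 days passed without each of 4, and B cells at 48 h without each of 2. Conventional dendritic cells at 48 h ran from -0.21 to -0.067 and did not pass. Antigen presentation genes moved little, with MHC class I at 0.0077 and -0.034 and MHC class II at 0.026 and -0.040, and the interferon gamma response was at -0.047 and -0.036. Slide as a block brought some of them past the threshold: at 48 h B cells at 0.49 and MHC class I and II at 0.095 and 0.16 (camera adjusted p = 0.00427, 0.0214 and 0.000950), and at 10 days regulatory T cells at -0.25 (camera adjusted p = 0.0412). With an estimated correlation none of them passed in the blocked fit (adjusted p = 0.670, 0.670, 0.646 and 0.569). At 48 h B cells were at -0.33 within slide 1 and 1.49 within slide 2, MHC class I at -0.033 and 0.17 and MHC class II at 0.024 and 0.20, and at 10 days regulatory T cells at 0.0082 and -0.29. The B cell value rests on 48 h replicate 5, the only 48 h array on slide 2: without it the shift was -0.20, and -0.092 with the block. Without vehicle replicate 2 it was -0.080. In the blocked fit MHC class I did not pass without each of 5 of the 16 arrays, nor regulatory T cells without each of 9, while MHC class II passed throughout.

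Of the myeloid groups beside macrophages and granulocytes, monocyte markers were at -0.016 at 48 h and -0.14 at 10 days, immunosuppressive myeloid genes at -0.074 and -0.14, and the CD11b and beta2 integrin list at -0.18 and -0.28 (camera adjusted p = 0.919 and 0.257), with medians of 0.012 and -0.047 and 5 of 10 genes lower at 48 h and 8 of 10 at 10 days. None of these passed with all arrays in, though at 10 days each of the 3 lists passed without 1 of the 16 arrays. Without single arrays the integrin shift at 48 h ran from -0.23 to -0.085. Blocked on slide, the immunosuppressive genes were at -0.22 at 10 days (camera adjusted p = 0.0256, and 0.569 with an estimated correlation). That blocked call was lost without each of 4 of the 16 arrays. With the block monocytes were at 0.070 and -0.077, and the integrin list at -0.12 and -0.25. Fibroblast markers were at -0.27 and -0.11, and fibrillar collagens and matrix genes at -0.25 at both times; with slide as a block fibroblasts had -0.46 at 48 h (camera adjusted p = 0.00428) and -0.24 at 10 days (camera adjusted p = 0.0322), and the matrix genes -0.54 (camera adjusted p = 0.00428) and -0.45 (camera adjusted p = 0.00254). With an estimated correlation neither passed in the blocked fit, with adjusted p = 0.646 and 0.569 for fibroblasts and 0.670 and 0.584 for matrix genes. The 10 day shift within slide 1, with its single vehicle array, was 0.047 for fibroblasts and 0.017 for matrix genes, and within slide 2 -0.44 and -0.79; the 48 h shifts were -0.34 within slide 1 for both and -0.32 and -0.28 within slide 2. One array carries the 10 day shifts: without 10 day replicate 5 fibroblasts were at 0.075 and matrix genes at 0.10. With the block they were then at -0.0029 and 0.045, where neither passed. Over all arrays left out singly, the blocked 10 day call was lost for 5 of 16 for fibroblasts and for 2 for matrix genes. At 48 h fibroblasts and matrix genes were at -0.45 and -0.51 without 48 h replicate 3. The weakest shifts without a single array were -0.19 for fibroblasts and -0.073 for matrix genes. The blocked 48 h calls were lost without vehicle replicate 1 for both and without 48 h replicate 4 for matrix genes. Of the fibroblast genes 12 of 19 also stand in another list.

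Erythroid markers were lower than in vehicle at both times, and vehicle replicate 3 stood 2.36 above the other vehicle arrays. Without it the 10 day shift was -0.88 ± 0.45 (SE over array means; camera adjusted p = 0.000308; adjusted p = 0.784 with an estimated correlation; exact permutation p = 0.0714), a ratio of 0.691 to the shift with it, and the 48 h shift -0.72 (exact permutation p = 0.183). That array may account for part of the difference, and the standard error leaves open how much; blood left in the tissue and a treatment effect were not tested apart.

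Macrophage markers varied least among arrays of a group of all lists but 1, with a median within-group SD of 0.0605. Lists of like brightness varied about as little: 10000 random lists matched on signal had a median of 0.0761 and a 5th percentile of 0.0473. Brightness could thus account for this SD, which lies between them, though matched lists were not compared with dimmer ones. The scaling matters as well, since with median centring in place of the 75th percentile the SD was 0.173, above the matched lists' median of 0.159. The small shift of these markers at 48 h may thus owe its low spread to a scaling point among bright probes, and no biological explanation was tested.

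Random splits of the arrays show that chance cannot be excluded for the counts of lists against vehicle. At 48 h 68 of 100 splits, the real one included, gave as many lists as the real 6, with 20 in the highest other. At 10 days 53, counted in the same way, gave as many as the real 9, with 25 in the highest other. For genes the real count was 0 in each of the 3 comparisons, which all 100 of 100 splits reach whatever the data, so these counts test nothing; the highest other splits gave 375 genes at 48 h, 12 at 10 days and 1 between 10 days and 48 h. The split with 375 genes set 48 h replicates 3 and 4 and vehicle replicates 2, 3 and 5 against the other 6 arrays; a split so far above the real count points to a structure among the samples, but it is the highest of 100 drawn, 8 of which gave any gene. Its 5 arrays have the 5 lowest scores of the 11 on the second principal component, from -63.2 to 0.482 against 11.49 or more, and what lies behind that component was not tested. These splits do not keep the slides. With slide as a block and each slide's group sizes kept, chance cannot be excluded either: 5 of 30 splits gave as many lists as the real 15 at 48 h, with 18 in the highest other, and 13 of 84 as many as the real 16 at 10 days, with 22 in the highest other. A split of these 11 arrays by slide gave 1 gene and 10 lists, more than the real split. It differs from the real split only in vehicle replicate 1 and 48 h replicate 5, so it cannot set slide apart from treatment. The random splits at 48 h gave 1 to 20 lists, a range that holds these 10. With slide as a block 0 genes and 15 lists passed at 48 h.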
